A study of Caenorhabditis elegans with 2 samples.

How the data were processed

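Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Caenorhabditis elegans at the L3 larval stage, with the sexes mixed. Per the labels, the worms were of strain OP54, which carries unc-119(ed3) and the integrated array wgIs54, an insertion that targets egl-5. The labels describe the target as an eGFP fusion of EGL-5, a posterior homeodomain protein of the Hox family. The 2 samples were labelled as biological replicates 1 and 2 of 1 group, and no untreated, untagged or input sample formed a group of its own. A control experiment is named in the labels and was not analysed here. The labels give a library fragment size range of 150 to 350 bp. They name a pair of instrument models for replicate 1 and none for replicate 2, so a sequencing batch could not be assigned.

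The authors deposited peak lists in narrowPeak form for each replicate, for both replicates together and after thresholding by the irreproducible discovery rate (IDR), a measure of how well the ranks of peaks agree between replicates. Per the file headers in the deposited notes, the replicate and pooled lists hold peaks and background and were the input to IDR, and the thresholded list is the optimal set. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each peak in the deposited lists has a score in its signal column, whose scale is the authors' own, and it was used only to rank, filter or describe peaks within a list. The deposited lists also give a −log10 q-value per peak, which reached its maximum of 3.54 in 67.3% of the IDR peaks and was therefore not used for ranking. Lists were deposited on the ce11 and ce10 builds. The ce11 lists were used throughout, and no coordinate was converted; ce10 lists served only for counts, scores by rank and overlap among themselves. Chromosome names in the ce11 lists matched those of the reference, and no peak ended beyond a chromosome's length.

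Read counts are not part of these lists, so the sequencing depth behind each peak is unknown and no interval for a single peak can be given. Intervals on shares of peaks or genes are exact binomial (Clopper-Pearson) 95% intervals and cover counting error only. The peak width was 364 bp for all but 9 of the 2570 IDR peaks, so widths carry no measurement of the extent of binding. The IDR list held exactly the 2570 highest-scoring of the 28619 pooled peaks, and the remaining 26049 are called weaker peaks here. The pooled list, with a median score of 10.5 and −log10 q-values down to 0.0177, is labelled as peaks and background. Weaker peaks can therefore include background regions and are not taken as weaker binding.

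The replicate names differ between builds. Scores at equal rank in the ce11 list of replicate 1 differed from the ce10 list of replicate 1 by a median of 39.3%, and from the ce10 list of replicate 2 by 0.218%. For replicate 2 on ce11 the values were 64.6% against replicate 2 on ce10 and 0.341% against replicate 1. Replicate numbers below follow the ce11 lists, and which biological sample each number belongs to could not be settled.

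Gene models came from Ensembl release 115 on WBcel235, the assembly called ce11 in genome browsers, with 19973 protein-coding genes and 29314 protein-coding transcript starts. Only the 6 nuclear chromosomes were used. A promoter window ran from 1000 bp upstream to 200 bp downstream of any protein-coding transcript start. Genes with more annotated starts therefore had more windows, and no comparison of gene lists adjusted for the number of starts. Each summit was placed in a promoter window, otherwise an exon, otherwise an intron, otherwise intergenic sequence. Annotated starts of worm genes are often trans-splice sites, and genes within operons share an upstream promoter, so distances are to annotated starts and not to initiation sites.

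Replicate agreement was the share of the N highest-scoring peaks of replicate 1 that overlapped, by at least 1 bp, the N highest-scoring peaks of replicate 2, with N equal to the number of IDR peaks. It was set against 1000 draws in which the positions of replicate 2 were shuffled within chromosomes (permutation test, one-sided). Location was compared with 1000 draws of random positions within the same chromosomes (permutation test, two-sided) and with the weaker peaks (Fisher's exact test). Scores of promoter peaks and other peaks were compared by a permutation test of the difference in medians with 100000 resamples, two-sided. Chromosomes were tested by exact binomial tests against their share of genome length and of protein-coding genes. For 24 gene lists, the number of genes with an IDR summit in the promoter window was compared with all other protein-coding genes by two-sided Fisher's exact tests. Every member fixed for the lists was found in the annotation. For 11 motifs, the share of summits with the motif within 50 bp on either strand was compared with flanks 200 to 300 bp away, by an exact McNemar test against a flank drawn at random. After seeing the data, this draw was repeated 1000 times, and location p-values were also computed exactly from the sum of binomial counts over chromosomes. The motif's ratio of centre to flank was also ranked among all rearrangements of its own bases. Benjamini-Hochberg adjustment ran over the 6 chromosomes, the 24 lists and the 11 motifs separately, and the threshold was an adjusted p of 0.05. Neighbouring genes can share a peak, and neither genes nor peaks are independent replicates, so these p-values describe these lists and not the spread between worm cultures.

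Genes were named by a fixed rule. It took the genes at the 20 highest-scoring promoter peaks, every member of the Hox list, and the 4 members with the highest-scoring promoter peaks in each other list. It also took the nearest gene of the 5 highest-scoring peaks outside promoters, egl-5 and unc-119, and neighbours of egl-5 within 20 kb with a promoter peak. Samples, tests, lists, motifs, the naming rule and the alternatives listed first below were fixed before the data were examined. The alternatives were a stricter set of the 1285 highest-scoring IDR peaks, each replicate's list alone, other overlaps, promoter windows of 500 and 2000 bp upstream, and assignment to the nearest start. Others were a background of 10000 gene sets matched on upstream length, a wider motif window, promoter peaks or other peaks alone, merged peaks and the ce10 lists. Leaving out the peaks within 20 kb of egl-5, requiring support in the top peaks of each replicate, and leaving out peaks within 200 bp of tRNA genes were chosen after seeing the data.

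The scripts were tested on simulated data. All 200 planted promoter genes were recovered (100%), and 2.8% of 500 random lists of 20 genes had an unadjusted p under 0.05. With shuffled peaks, 0 of the 24 lists and 0 of the 11 motifs passed the threshold. Shuffled positions have neither the promoter preference nor the higher share of G and C of the real summits. This check therefore does not bound false calls at the real summits. TTTATG planted at 20% of 2570 shuffled summits gave an excess of 18.7 percentage points. With 50% of the 2570 peaks copied, 51.1% overlapped. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.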

Results

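The binding of eGFP-tagged EGL-5 was measured by ChIP-seq in whole L3 larvae. EGL-5 is an Abdominal-B-like Hox protein of the worm that acts in the tail region, including rectal cells and male tail lineages, and in the HSN motor neurons. The 2 biological replicates belong to 1 group, and the peak lists give no read depth. The set kept by the authors after IDR held 2570 peaks on ce11, with a median score of 40.97 and a range of 30.8 to 510. The lists of replicate 1 and replicate 2 held 30000 peaks each, and the pooled list held 28619. With 1 group and no control group, the comparisons implied are between replicates, between bound regions and the rest of the genome, and between groups of genes.

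The 5 highest-scoring peaks in the genome all lay around egl-5 itself, on chromosome III. The highest, at 7819891 to 7820286, had a score of 509.8 and lay in intergenic sequence 5700 bp downstream of the nearest egl-5 start. Next came a peak at 7812410 to 7812953, with a score of 424.2, in intergenic sequence with its summit at -1666 bp from the egl-5 start. The peak at 7824050 to 7824461 scored 396.7 with its summit between egl-5 and egl-45, which encodes a subunit of a translation initiation factor, and its edge over the 3′ end of egl-45. Peaks at 7819086 to 7819250 and 7806965 to 7807328 scored 189.5 and 179.2, both intergenic. The highest score anywhere else was 165.9.

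The egl-5 gene (WBGene00001174) spans 7814374 to 7817141 on the plus strand. Its promoter window held a peak at 7814143 to 7814506 with a score of 118.4, its summit at -49 bp from the start. In all, 17 IDR peaks lay within 20 kb of the gene, over 25.8 kb, with a median score of 93.0, and 8 of them were among the 50 highest scores. Of the neighbours with a promoter window in this region, kcmf-1 and egl-45 shared a peak at 7828952 to 7829315 with a score of 93.0. The 3 highest peaks had scores of 221.8, 189.2 and 150.6 in replicate 1 and 290.9, 232.2 and 248.0 in replicate 2. The strain carries added egl-5 sequence in the tagged insertion, in a number of copies not known here. Reads from the insertion and from the native locus are not separated in these lists. The unc-119 gene, at 10902641 to 10908935 on chromosome III and mutated in this strain, had no promoter peak. Its nearest IDR summit was 20435 bp away.

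**Figure D1:**
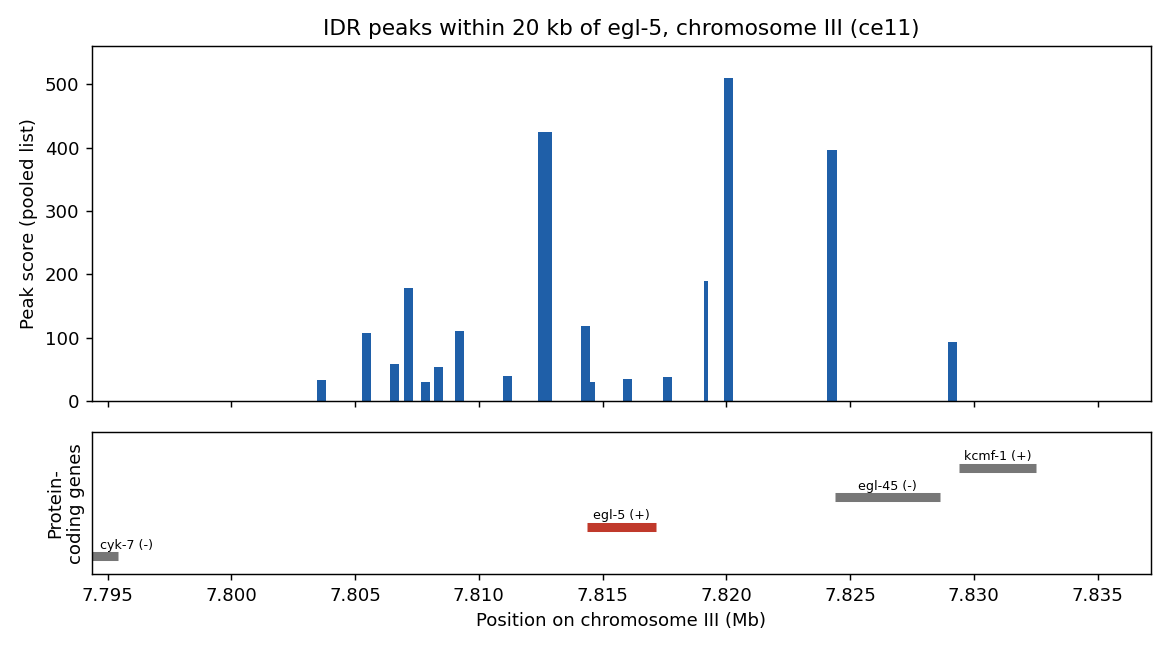
IDR peaks within 20 kb of egl-5 on chromosome III of ce11, drawn at their position in Mb with height equal to the authors' score in the pooled list, above the protein-coding genes with their strands. The 3 highest peaks, at 509.8, 424.2 and 396.7, lie on both sides of egl-5 and above the promoter peak at 118.4.

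Whether the replicates marked the same regions was asked next. Of the 2570 highest-scoring peaks of replicate 1, 1393 (54.2%) overlapped one of the 2570 highest of replicate 2. Shuffled positions gave a mean of 1.92% and a maximum of 2.80% (permutation p = 0.001, the smallest that 1000 draws can give, one-sided). Of the IDR peaks, 99.1% overlapped some peak of replicate 1 and 99.8% some peak of replicate 2, but 70.3% and 80.7% overlapped their 2570 highest peaks, and 1371 peaks (53.3%) did so in both.

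The 3 highest egl-5 peaks had the highest scores of the IDR peaks in each replicate. In contrast, 3 others of the 17 at the locus had low replicate 1 scores of 4.40, 5.81 and 8.03, where that list's median was 4.28. Across 2542 IDR peaks present in both lists, Spearman's rho between the scores was 0.183, and it was 0.177 over the 2525 peaks outside the egl-5 locus. Across the 14698 pooled peaks present in both lists, rho was 0.551. The IDR peaks are by construction the upper end of the pooled score, which narrows their range, and peaks are not independent replicates. The pooled score of the IDR peaks had a rho of 0.632 with replicate 1 and 0.759 with replicate 2.

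**Figure D2:**
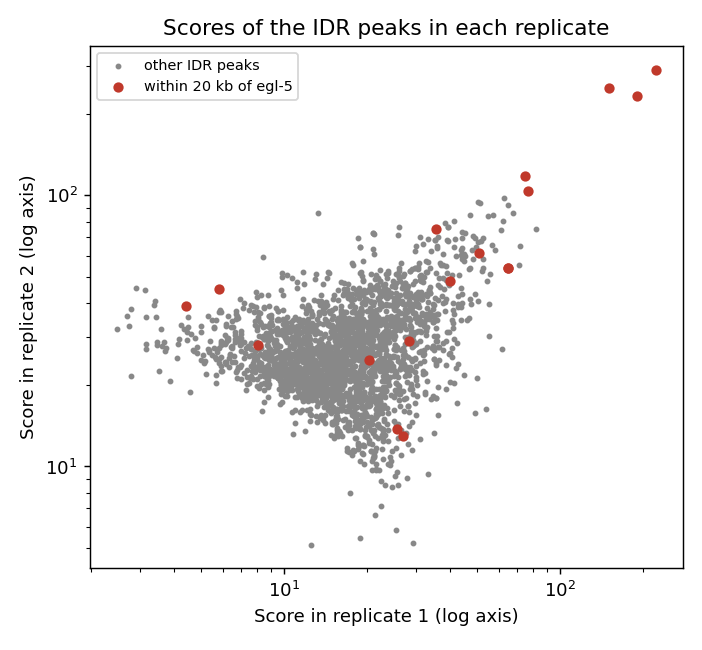
Score of each IDR peak in replicate 1 (x, log axis) against replicate 2 (y, log axis), for peaks present in both lists, with those within 20 kb of egl-5 in red. The 3 highest egl-5 peaks stand apart at 150.6 to 221.8 and 232.2 to 290.9, and the other peaks form a broad cloud with a rho of 0.177.

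Promoters held 1389 of the 2570 summits (54.05%, 95% interval 52.1 to 56.0). The highest promoter peak belonged to nspc-17 on the X chromosome, with a score of 155.5. Next were dld-1, which encodes dihydrolipoamide dehydrogenase, with 146.2, and the region between tbb-1, a beta-tubulin gene, and rib-2, with 146.0. The promoters of rps-28 and its neighbour Y41D4B.4 shared a peak with a score of 144.9. Peaks between rpl-12 and lin-54 and at tub-2 and Y71G12A.5 scored 132.8 and 130.6.

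Further high promoter peaks lay at iff-2, an eIF-5A gene whose peak is shared with F54C9.14 (125.9), the helicase gene hel-1 with C26D10.4 (121.7), and eef-1A.1, an elongation factor gene, with rfc-4 (119.96). The RNA-binding protein genes hrpa-1 and rbm-39 had scores of 118.8 and 116.9. The remaining genes at the 20 highest promoter peaks were egg-5 (121.5), C06B3.6 and C06B3.7 (114.1), malt-1 and ceh-38 (112.8), F02E9.5 (112.7), R05D3.8 and rfp-1 (112.03), acr-7 (108.6), C37A2.8 and E02D9.1 (107.1) and rpl-3 (106.3), beside egl-5 itself.

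Of random positions, 25.6% fell in promoters, so the observed share was 2.11 times higher (permutation p = 0.002, the smallest that 1000 two-sided draws can give). Among weaker peaks the share was 32.9% of 26049 (odds ratio 2.40, Fisher's exact p = 2.32e-97). Exons held 42 summits (1.63%) against 21.6% of random positions, and introns held 440 (17.1%) against 27.6%, both with the same permutation p of 0.002. Without replicate 2 the exon share was 3.11%. Intergenic sequence held 699 summits (27.2%) against 25.2% (permutation p = 0.012), and this excess was lost in 4 of the alternatives, among them the set without the egl-5 locus (permutation p = 0.052). Computed exactly, after seeing the data, these p-values were 0.0187 and 0.0540, so both lie near the threshold. Promoter summits lay at a median of -199 bp from the nearest start, with quartiles at -381 and -94 bp. Of the promoter summits, 437 (31.5%) fell in windows of 2 or more genes, so a peak there cannot be given to a single gene. In total 1781 of 19973 protein-coding genes (8.92%) had a promoter peak. Median scores were higher at promoters, at 42.7 against 39.7 elsewhere (difference 2.99, permutation p = 1e-05, the smallest that 100000 resamples can give). The difference was 3.39 with a window of 500 bp and 1.74 with 2000 bp (permutation p = 0.0064 for 2000 bp). The very highest scores lay outside promoters, and the highest promoter peak, at nspc-17, ranked 9 among the IDR peaks.

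The X chromosome held more peaks than its length gives, and chromosome V held fewer. X had 603 peaks, or 34.0 per Mb, which is 1.33 times its share of the genome (adjusted exact binomial p = 3.65e-13). Chromosome III had 437 peaks (ratio 1.24, adjusted exact p = 6.76e-06). Chromosome V had 354 (ratio 0.660, adjusted exact p = 1.25e-19) and chromosome IV had 369 (ratio 0.823, adjusted p = 4.22e-05). Chromosome I, with 414 (ratio 1.07, adjusted exact p = 0.155; 1.10 and 0.0403 without replicate 2), and chromosome II, with 393 (ratio 1.00, adjusted exact p = 0.934), did not pass the threshold by length. Against their share of protein-coding genes, chromosome I passed above 1 (ratio 1.12, adjusted exact p = 0.0157) and chromosome II below 1 (0.886, p = 0.00931). On X, 43.6% of the peaks lay in promoters and 340 lay elsewhere, whereas on the autosomes the promoter share ran from 54.8% on V to 60.6% on I. The share was lower on X than on the autosomes together, at 57.2% (Fisher's exact p = 4.87e-09, a test chosen after seeing the data). Per bp of promoter sequence, also computed after seeing the data, peaks were 1.35 times as frequent on X (exact 95% interval 1.18 to 1.54).

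**Figure D3:**
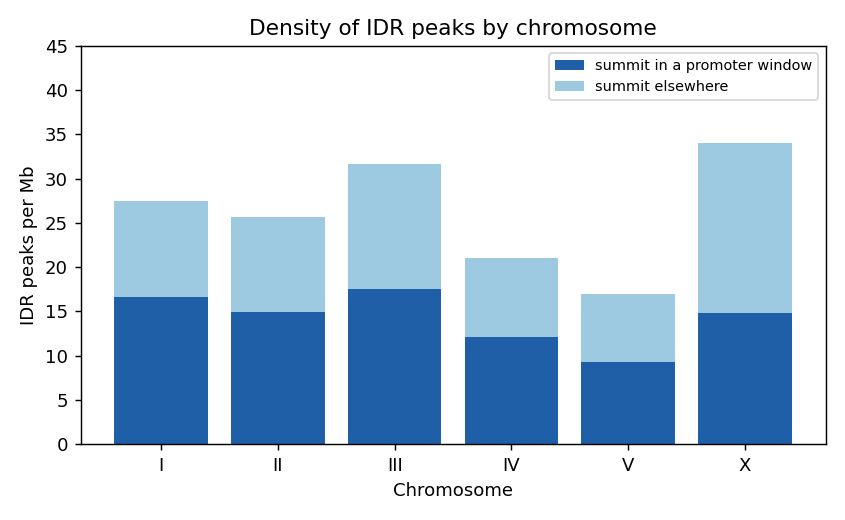
IDR peaks per Mb on each chromosome, split into peaks with the summit in a promoter window (dark) and elsewhere (light). X has the highest density, 34.0 per Mb, and V the lowest, 16.9 per Mb.

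Promoter peaks were then examined by gene list, with lists fixed by pathway, tissue or gene name and not by known EGL-5 targets. Of the 10 Hox genes and Hox cofactors, 3 had a promoter peak: egl-5, mab-5 and ceh-20. The mab-5 peak, at 7784178 to 7784541 on chromosome III, scored 59.4 and lay at -906 bp from the start of the gene, which acts in the posterior body next to the egl-5 domain. The peak at ceh-20, which encodes a Pbx-type cofactor, scored 30.9 and ranked 2549 of the 2570 peaks, near the lowest score kept. The genes ceh-13, lin-39, nob-1, php-3, ceh-40, ceh-60 and unc-62 had none in the window, although lin-39 and unc-62 were the nearest genes of peaks scoring 66.1 and 53.0. The share of 30% against 8.91% of other genes did not pass the threshold (Fisher's exact adjusted p = 0.158). With each summit given to its nearest start, the ratio was 4.70 and passed (adjusted exact p = 0.00867), against 3.37 in the promoter window and 2.21 there without replicate 1. With a window of 500 bp it was 1.41 (adjusted exact p = 0.762). The counts in the promoter window and with nearest starts include egl-5 itself, whose signal is not separated from that of the tagged insertion. Apart from egl-5, the promoter peaks were those of mab-5 and ceh-20 only.

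Wnt pathway genes held promoter peaks more often than other genes, in 7 of 26 cases (26.9%, ratio 3.03, Fisher's exact adjusted p = 0.0307). Among them were mig-5 (100.9) and dsh-1 (69.6), which encode Dishevelled proteins, cam-1, a Ror receptor tyrosine kinase (65.9), and lin-17, a Frizzled receptor (52.9). The call was lost without replicate 1 (ratio 2.55, adjusted exact p = 0.0888), with a window of 500 bp (ratio 1.62, adjusted p = 0.762) and with support required in each replicate (ratio 3.76, adjusted p = 0.0681). It rests on few genes. The peaks of dsh-1, cam-1 and lit-1, another of the Wnt genes counted, lay inside the gene, upstream of an internal transcript start. So did those of egl-27, sma-9 and act-4, named below. Genes with several starts have more windows, and the share was not adjusted for this.

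Cytoplasmic ribosomal protein genes had the highest share of the 24 lists. Promoter peaks stood at 61 of 78 genes (78.2%, 95% interval 67.4 to 86.8) against 8.65% of other genes, a ratio of 9.05 (Fisher's exact adjusted p = 1.18e-47). The highest scores were those of rps-28 (144.9), rpl-12 (132.8), rpl-3 (106.3) and rpl-15 (106.1). The call held under every alternative run, with ratios from 4.39, with nearest starts, to 13.6, with the 1285 highest-scoring peaks.

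Lists of tissues and fates in which egl-5 acts held promoter peaks at shares that were not told apart from the 8.92% of all protein-coding genes. In rectal and hindgut development 1 of 9 genes (11.1%) had a peak, egl-27 (66.5), and in male tail development 1 of 13, mab-20, a semaphorin gene (30.9). Of 14 touch receptor neuron genes only mec-5 had one (32.2), and the 11 genes of the HSN and serotonergic neurons had 0, which allows a share of up to 28.5% by the exact binomial interval. In the Sma/Mab TGF-beta pathway 1 of 11 genes had a peak, sma-9 (68.4). Without replicate 1 or with a window of 500 bp the touch receptor list had no promoter peak, and without replicate 2 the male tail list had none. Neither had one in the 1285 highest-scoring peaks or with support in each replicate. With nearest starts the male tail share turned above that of other genes, also without passing. None of these lists passed the threshold in either direction (Fisher's exact adjusted p from 0.806 to 1), and their sizes leave wide intervals. The samples were whole larvae of mixed sexes, so binding confined to few cells or to males may not reach a called peak.

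Muscle, heterochronic, Notch and neuronal lists had shares above those of other genes without passing the threshold. Body wall muscle had 5 of 23 (21.7%, unadjusted Fisher's exact p = 0.0486, adjusted p = 0.158), among them act-4 (81.4), the myogenic factor gene hlh-1 (50.4), unc-112 (43.5) and pat-10 (36.3). The heterochronic pathway had 3 of 11, lin-28 (42.7), alg-1 (41.3) and lin-14 (40.4), with an adjusted Fisher's exact p of 0.181. The Notch pathway had 2 of 10, the receptor gene glp-1 (48.0) and sup-17 (31.7), with an adjusted exact p of 0.533. Pan-neuronal genes had 2 of 15, ric-19 (72.0) and snb-1 (37.3), with an adjusted exact p of 0.806. Muscle, heterochronic and pan-neuronal genes each passed in some alternatives. With nearest starts the ratios were 4.10, 5.13 and 3.76. Without replicate 1, pan-neuronal genes had a ratio of 3.69 (adjusted exact p = 0.0402), against 1.496 with both replicates and 2.56 without replicate 2. Without replicate 2, muscle had 3.35 and the heterochronic pathway 4.67 (adjusted exact p = 0.0376 for each). The Notch ratio was 2.24, and it was 1.10 without replicate 1 and 3.85 without replicate 2. With a window of 500 bp the heterochronic ratio fell from 3.06 to 1.28 and the Notch ratio to 1.41.

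No promoter peak was found at the 13 vulval Ras pathway genes, the 15 programmed cell death genes, the 17 cuticle collagens, the 13 intestine, 14 pharynx and 18 germ line genes. Taken singly these counts of 0 did not pass the threshold (Fisher's exact adjusted p from 0.736 to 0.806), and the exact interval for the 13 intestine genes reaches 24.7%. The absence at cell death genes did not hold with a replicate left out. That at vulval Ras, cuticle collagen and pharynx genes did not hold with nearest starts. In the epidermis and seam list 1 of 11 genes had a peak, rnt-1 (51.9), with an adjusted exact p of 1.

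Some large gene families had fewer promoter peaks than other genes. The chemoreceptor families str and srh had 2 of 413 (0.484%, ratio 0.0532, Fisher's exact adjusted p = 2.11e-13), srh-16 (43.7) and srh-89 (40.95), and this held under every alternative run. The col collagens had 4 of 156 (ratio 0.286, adjusted exact p = 0.0204), namely col-38 (63.9), col-8 (47.2), col-71 (46.3) and col-34 (33.0). Nuclear hormone receptors had 11 of 269 (ratio 0.455, adjusted exact p = 0.0204), with the highest scores at nhr-49 (50.2), nhr-256 (49.2), nhr-57 (46.9) and nhr-48 (46.9). Both calls were lost without replicate 2, at an adjusted p of 0.100 for col and 0.0853 for nuclear hormone receptor genes, and with support in each replicate (0.272 and 0.0681). The col call was also lost in the 1285 highest-scoring peaks (0.327), and that of the nuclear hormone receptors with nearest starts (0.181). Where a call was lost, the share still lay below that of other genes. Histones had 1 of 72, his-37 (63.9), with an adjusted exact p of 0.0804 and a ratio of 0.155, which was 0.306 without replicate 1 and 0.711 without replicate 2. Matched on upstream length, the histone ratio was 0.0961 and passed, and histones passed with nearest starts too. Homeobox genes named ceh had 5 of 63 (adjusted exact p = 1), led by ceh-38 (112.8), ceh-92 (44.7), ceh-100 (37.8) and ceh-39 (35.1).

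**Figure D4:**
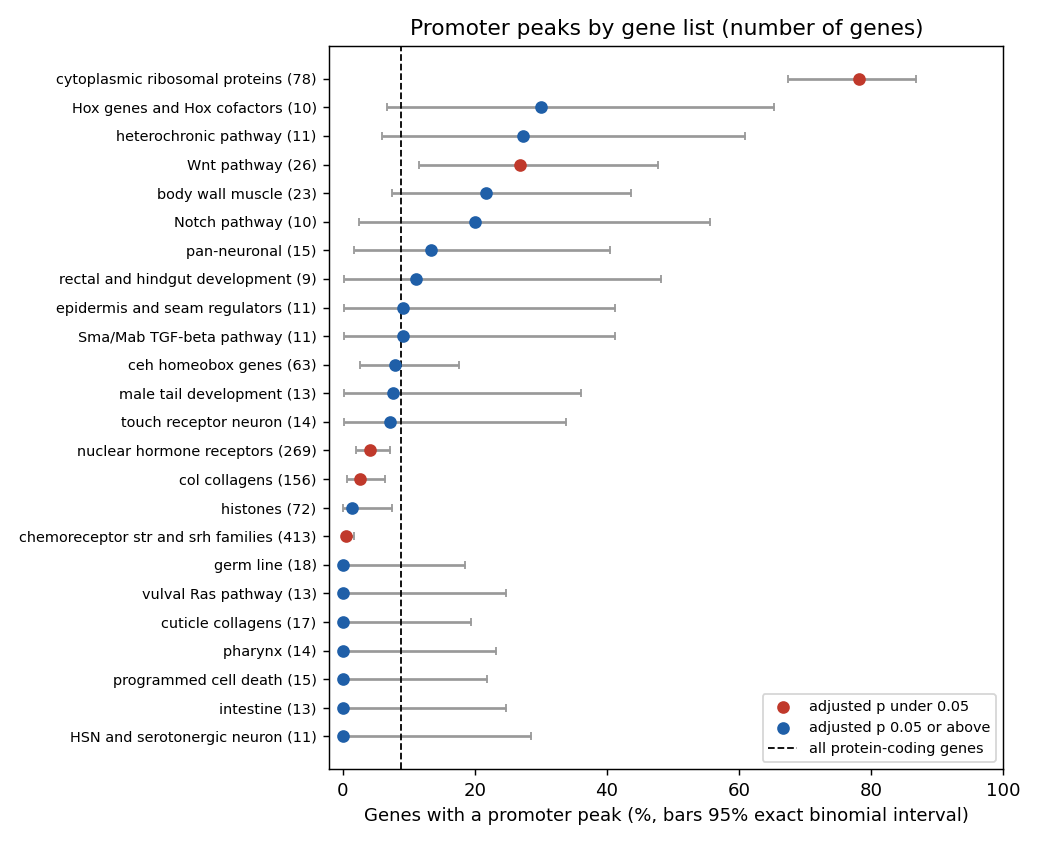
Percentage of genes in each fixed list with an IDR summit in the promoter window, with 95% exact binomial intervals as bars, list sizes in parentheses and lists past an adjusted p of 0.05 in red. The dashed line marks the 8.92% of all protein-coding genes; ribosomal protein genes stand at 78.2%.

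Which sequences lay at the summits was tested with 11 motifs. The GAGA repeat GAGAGA was the most enriched, in 26.8% of summits against 7.84% of flanks (ratio 3.42, adjusted exact McNemar p = 1.99e-79). The E-box CAGCTG followed, in 4.75% against 2.04% (ratio 2.32, adjusted exact p = 1.36e-06). Among rearrangements of their own bases these ratios stood at percentiles 94.7 and 85.1. Among weaker peaks the GAGAGA values were 10.7% and 6.61%.

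The posterior Hox hexamer TTTATG was in 11.3% of summits against 8.81% of flanks (ratio 1.28, adjusted exact McNemar p = 0.0219), the highest ratio among the 29 rearrangements of its bases. The excess lay outside promoters, in 15.2% of 1181 summits against 8.85% of flanks (ratio 1.72, adjusted exact p = 3.77e-06), while promoter summits gave 7.99% against 8.78% (ratio 0.910). The share of summits with TTTATG differed between these classes (Fisher's exact p = 1.03e-08, a test chosen after seeing the data). The overall call was lost without replicate 2 (ratio 1.06, adjusted exact p = 0.595), in the 1285 highest-scoring peaks (1.16, p = 0.588), with support in each replicate (1.21, p = 0.545) and within 100 bp (1.17, p = 0.0614). These p-values rest on 1 random draw of flanks, so 1000 further draws were made after seeing the data. The overall call passed in 95.8% of them, with a median adjusted exact p of 0.00524 and 95% of values from 0.000111 to 0.0571. It passed in 0.3% of draws without replicate 2, in 2.7% in the 1285 highest-scoring peaks and in 13.3% with support in each replicate, but in 84.5% within 100 bp, so the loss there belongs to the draw used.

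The other posterior hexamer, TTTATT, was less frequent at summits than in flanks, at 15.95% against 25.2% (ratio 0.634, adjusted exact McNemar p = 6.29e-13). TTTAC (ratio 0.682, adjusted exact p = 1.23e-10), the central Hox motif TAATTA (0.233, adjusted p = 3.73e-16) and the GATA motif AGATAA (0.568, adjusted p = 1.42e-06) were also less frequent. G and C made up 45.3% ± 6.86 (SD, n = 2570 peaks) of the bases at summits and 34.9% ± 6.18 in flanks. Among rearrangements of the same bases, TTTATT stood at percentile 80, TTTAC at 47.4, TAATTA at 23.1 and AGATAA at 37.9. The rearrangements numbered only 5, 19, 13 and 29 in that order. The Hox-Pbx sites TGATTTAT (ratio 1.22), TGATTGAT (1.76) and TGATTAAT (0.500) and the Meis-like TGACAG (1.24) did not pass the threshold, with adjusted exact p from 0.0792 to 0.896. Over the 1000 draws these motifs passed in 0.5% (TGATTTAT) to 25.8% (TGATTGAT). Against rearrangements of their own bases they stood at percentiles 98.8 (TGATTTAT), 95.9 (TGATTGAT), 87.1 (TGATTAAT) and 63.1 (TGACAG). Outside promoters, TGATTGAT was at 1.52% of summits against 0.508% of flanks (adjusted exact McNemar p = 0.0595). There TGATTGAT passed in 59.2% of the 1000 draws, and at promoters in 0%, so the call outside promoters depends on the draw.

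**Figure D5:**
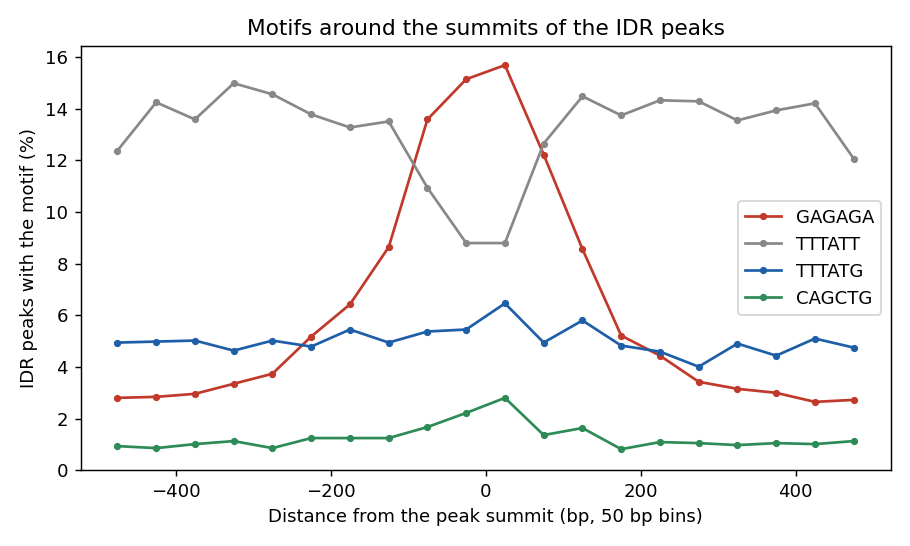
Percentage of the 2570 IDR peaks with each motif in bins of 50 bp from 500 bp upstream to 500 bp downstream of the summit on the plus strand. GAGAGA peaks at the summit, TTTATT falls there, and TTTATG and CAGCTG show small peaks.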

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

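Leaving out the egl-5 locus, requiring support in each replicate and leaving out tRNA genes were chosen after seeing the data; the other alternatives were planned. Of the comparisons run, 372 kept their direction and side of the threshold, 18 lost a call, 14 gained one, 21 changed direction and 2 counts moved. The promoter share, the X and V ratios and the ribosomal and chemoreceptor calls held throughout. Taking the top of the pooled list gave the IDR set itself, so only random draws differed there (intergenic permutation p of 0.012 and 0.022). The counts above include this setting, which by construction says nothing about stability. Replicate overlap ran from 47.8% to 58.1%. The depth is unknown, so its limit on weak or absent peaks cannot be stated. The cause of the changes below was not tested, except that smaller sets hold fewer peaks by construction.

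The number of peaks was 1285 in the stricter set and 1371 with support in each replicate. The intergenic excess was lost in the stricter set (25.4%), without the egl-5 locus (26.9%), with support in each replicate (26.4%) and with a 2000 bp window (18.9%). Against gene share, chromosome I passed (1.12) and II turned to 0.886 and passed; II was 0.981 in the stricter set and 0.929 with support in each replicate, and IV (0.874) lost its call in the stricter set. Leaving out a replicate gave 1.04 to 1.10 for I, which passed without replicate 2, and 0.998 to 1.01 for II.

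The col call was lost in the stricter set (0.372) and with support in each replicate (0.373), where Wnt (3.76) and nuclear hormone receptor genes (0.359) also lost theirs. With 500 bp, Wnt fell to 1.62, Hox and Notch to 1.41, heterochronic to 1.28, ceh to 0.446 and touch receptor to 0, and male tail turned to 1.08 and Sma/Mab to 0. With 2000 bp, muscle (2.60) and pan-neuronal genes (3.41) passed, and rectal (0.946), Sma/Mab (0.774) and epidermis genes (0.774) turned. With nearest starts, Hox (4.70), heterochronic (5.13), muscle (4.10), pan-neuronal (3.76) and, downwards, histone genes (0.130) passed, and nuclear hormone receptors (0.695) did not. There, male tail (2.89), vulval Ras (2.17), epidermis (0.854), cuticle collagen (1.10), pharynx (1.34) and ceh genes (1.04) turned without passing. Matching on upstream length gave 0.0961 for histones, which passed, and 1.15 for male tail. Without replicate 1, pan-neuronal genes passed and Wnt lost its call; without replicate 2, muscle and heterochronic genes passed and col and nuclear hormone receptor genes lost theirs. Leaving out a replicate gave 2.55 to 3.95 for Wnt, 2.56 to 3.69 for pan-neuronal, 3.02 to 4.67 for heterochronic, 2.89 to 3.35 for muscle, 2.21 to 3.85 for Hox, 1.10 to 3.85 for Notch, 0.306 to 0.711 for histones, 0 to 0.914 for touch receptor, 0 to 0.850 for male tail, 0.736 to 1.71 for cell death, 0.525 to 1.02 for ceh, 0.489 to 0.520 for nuclear hormone receptor and 0.211 to 0.408 for col genes.

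TTTATG lost its call in the stricter set (1.16), with support in each replicate (1.21) and with 100 bp (1.17), turned at promoters (0.910), and ran from 1.06 to 1.33 without a replicate. TGATTTAT was 0.929 with support in each replicate and 1.00 at promoters, where TGATTAAT (0.308) passed. Over 1000 draws of flanks, made after seeing the data, TTTATG passed in 84.5% with 100 bp and TGATTAAT in 45.2% at promoters, so these changes rest on the draw used. Outside promoters TGATTGAT missed the threshold in the draw used (adjusted exact McNemar p = 0.0595) but passed in 59.2% of the 1000, so its result there rests on the draw too.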

Other observations

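The gene families, non-coding classes and heptamers described here, and the tests of weaker peaks at egl-5 and on X, of peaks per bp on X and of tissue genes as a separate group, were chosen after seeing the data. Among 175 families of at least 10 genes that share a symbol stem, 16 held promoter peaks more often and 16 less often than other genes (Fisher's exact test, adjusted over the families). Beside the ribosomal protein genes, proteasome regulatory subunits (rpn) had 10 of 13 genes with a promoter peak (adjusted exact p = 4.03e-07). The secretory pathway genes named sec had 8 of 19 (adjusted exact p = 0.00265), cytochrome c oxidase genes (cox) 6 of 15 (0.0154), vacuolar sorting genes (vps) 9 of 31 (0.0154), nuclear pore genes (npp) 8 of 26 (0.0166) and mitochondrial ribosomal genes (mrpl) 10 of 41 (0.0235). Stems named for mutant phenotypes were also among the 16, with 13 of 47 lin genes (adjusted exact p = 0.00295) and 19 of 94 unc genes (0.0103). At the other end, C-type lectin genes (clec) had 5 of 240 (adjusted exact p = 0.000575), F-box genes (fbxa) 3 of 170 (0.00328), and the chemoreceptor families srw and srbc had 0 of 109 and 0 of 71 (0.00158 and 0.0235).

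Several classes of non-coding genes also lay under the peaks. Within 200 bp of tRNA genes stood 66 summits against a mean of 7.27 in 100 shuffles, at 75 of 612 genes, and 39 of the 66 were on X, as are 276 of the 612 genes. At snoRNA genes there were 50 summits against 4.71, with 1 on X, and at snRNA genes 11 against 1.59. Genes annotated as ncRNA had 427 against 92.5, lincRNA genes 20 against 7.87 and miRNA genes 8 against 2.94. Pseudogenes had 7 against 92.8 and piRNA genes 25 against 72.4 (permutation p adjusted over 10 classes = 0.025 for each of these 8 classes, from the smallest p of 0.02 that 100 shuffles can give). Outside promoter windows lay 50 of the 66 tRNA summits, 24 of the 50 at snoRNA genes and 4 of the 11 at snRNA genes. So did 232 of the 427 at ncRNA, 15 of the 20 at lincRNA and 3 of the 8 at miRNA genes. The shuffles did not keep the preference of the peaks for promoters, so they do not separate these classes from promoters nearby. Outside promoters, TTTATG, a motif fixed in advance, was at 15.9% of 340 X summits and 14.98% of 841 autosomal summits (Fisher's exact p = 0.721). The heptamers CTGCGTC, at 3.53% and 12.01%, and CCCTGCG, at 3.82% and 0.476%, were picked from these same peaks, so no test of them applies.

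The strongest peaks lay at egl-5, where extra copies in the integrated array and binding to Hox sites are candidate explanations. The relaxed pooled list had 32 peaks in the 40 kb around egl-5 against a median of 11 and a maximum of 46, the 99.4th percentile of 5004 windows. This lies above the percentile of 99 fixed in advance for copied DNA. However, the count includes the IDR peaks that raised the question, so it cannot decide. Weaker peaks alone, counted after seeing the data, numbered 15 against a median of 10, at percentile 76.1. That is below the same 99, a bound carried over to this later count. Hox hexamers TTTATT or TTTATG stood at 4 of 17 summits at the locus (23.5%) and at 25.6% elsewhere (Fisher's exact p = 1), and with 17 summits this neither excludes nor favours such sites. Extra copies, which weaker peaks neither show nor exclude, and autoregulation both stay open, and no control from this strain was analysed here.

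Peaks at ribosomal protein and similar genes may mark promoters active in many cells rather than sites chosen by EGL-5. Genes of the ribosomal protein, intestine, pharynx and germ line lists together held promoter peaks 5.72 times as often as other genes (61 of 123, Fisher's exact p = 1.10e-31), but all 61 were ribosomal protein genes. The 45 tissue genes had 0 (Fisher's exact p = 0.0312), but they were grouped after each list was seen to have 0 and no list passed alone, so signal at every active promoter and signal at promoters active in most cells cannot be told apart. Hox hexamers were at 13.3% of these summits and 23.1% of other promoter summits (Fisher's exact p = 0.0836), so a role of these sites cannot be told apart from none with 60 summits. Without a peak list of an unrelated factor, no biological explanation was tested further.

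By length, X held outside promoters 340 of 1181 peaks, 1.63 times its share of the genome (exact binomial p = 5.97e-21), and in promoters 263 of 1389, 1.07 times its share (p = 0.218). Per bp of each kind of sequence, peaks were 1.35 times as frequent on X in promoters (exact 95% interval 1.18 to 1.54), 1.55 times in introns (1.23 to 1.94) and 1.55 times in intergenic sequence (1.31 to 1.82), so promoters were in excess too. Upstream regions are longer on X, with a median of 2123 bp against 826 bp, but the odds ratio of a promoter peak over deciles of upstream length was 1.36 (95% interval 1.18 to 1.57), which together with the intergenic 1.55 argues against length as the whole cause for promoter or intergenic peaks. Weaker peaks were also in excess on X, at 1.25 times its share (exact binomial p = 3.79e-76), so the excess was not particular to the IDR peaks, and the step from 1.25 to their 1.33 lies within counting error (Fisher's exact p = 0.136). Whether a general excess of called regions accounts for all of it stays open, the ratio on X was 1.27 without peaks near tRNA genes, and no biological explanation was tested.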
